A study of Homo sapiens with 14 samples.

How the data were processed

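RNA was sequenced from 14 libraries of A549 cells, a human lung carcinoma line, in 7 groups of 2. In 12 of the libraries a siRNA and a viral construct had been introduced, and the other libraries were untreated cells. Groups and replicate numbers were taken from the sample labels. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

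Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.30 and aligned with TopHat2 2.0.12, and the genome build was GRCh37. The quantifier and the annotation release are not given in the sources used here. Per the file headers, each deposited table holds an FPKM per isoform (fragments per kilobase of transcript, scaled to the mapped fragments of the library) with lower and upper confidence bounds, and a status for each estimate. Scaling between libraries by the authors is not stated, and each library is on its own FPKM scale. Per the file headers, the same tables hold a coverage value per isoform. Within a library, coverage divided by FPKM was nearly constant, so its ratio gave the relative depth of the libraries, while the absolute number of reads is unknown. Low FPKM values ran on towards 0 without steps of whole reads, so no counts were recovered and no count model was used. Each table lists 195553 isoforms of 57756 genes.

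A gene's FPKM was the sum over its isoforms. Genes were tested with limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(FPKM + 1). A fold change is therefore on the log2(value + 1) scale, which understates changes of genes with low values. Genes needed a mean FPKM of at least 1 over all libraries, which 14244 genes had, and 14 genes of the files with an estimate not marked OK in some library were left out. The remaining 14233 genes entered a model with a mean for each of the 7 groups, so that all 14 libraries shared 1 estimate of the spread with 7 residual degrees of freedom and 3.92 prior ones. Isoform usage was an isoform's FPKM as a percent of its gene's FPKM. It was tested with the same model for 41727 isoforms of 11666 genes with a mean usage of 5 to 95 percent, and differences are in percentage points. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and an adjusted p under 0.05 was called. FPKM cannot tell the S34F allele from the wild-type one, or a transgene from the endogenous gene, and without a statement on strand, overlapping and antisense genes can share reads.

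Transcript types came from GENCODE release 29, matched by Ensembl identifier for 181425 isoforms and 52328 genes, including 39026 of the isoforms tested for usage. Gene coordinates are those of the deposited tables (GRCh37). Usage of a 3′ splice site, called an acceptor here, was the summed FPKM of the matched isoforms that use it as a percent of the summed FPKM of the gene's matched isoforms that span it, with exon structures from GENCODE release 29, and acceptor positions are in GRCh38. Matched here means an identifier and a length equal to those in that release, which 102715 of 116194 isoforms of the genes tested had. The other isoforms are missing from these percents. Spanning isoforms had to have a mean FPKM of at least 1 in sum, a condition added after the files were seen. In all, 31477 acceptors had variable usage by the same limits as isoforms. A genome sequence was not used here. The bases upstream of an acceptor were read from other annotated transcripts whose exons cover them, a source chosen after the files were seen, which gave bases for 53.9% of these acceptors. Of those, 99.4% had AG at the end of the intron, which left 16842 acceptors in 6973 genes. These are acceptors whose upstream bases lie in an exon of another transcript, so they are mostly alternative sites and not a sample of all introns. Position -3 is the base before the AG. Acceptors with an unadjusted p under 0.01 and a change of at least 5 points, 1 per gene (that with the smallest p), were sorted by base and direction. Acceptors with T and C were compared by a two-sided Fisher's exact test with 95% intervals, where an odds ratio above 1 means that acceptors with T were used less more often than acceptors with C.

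There were 22 gene lists fixed before the data were examined. They cover splice site recognition, SR proteins and hnRNPs, nonsense-mediated decay factors, genes known to splice differently with mutant U2AF1, G2/M and mitosis, G1/S and DNA replication, p53 targets, interferon-stimulated genes, NF-kB and inflammatory cytokines, the unfolded protein and integrated stress response, NRF2 targets, epithelial genes, mesenchymal and TGF-beta response genes, cholesterol biosynthesis, glycolysis and hypoxia response, autophagy, cytosolic ribosomal proteins, replication-dependent histones, mitochondrially encoded genes (as a sign of RNA quality), alveolar and airway markers, and markers of fibroblasts and of leukocytes and endothelium. Each was tested in 7 comparisons with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a comparison. Counts of members are given over all genes tested and adjusted over the list alone.

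The genes named were set by a rule written before the data were examined. It takes U2AF1 and U2AF2, the called genes with the largest rises and falls whose libraries on both sides did not overlap (10 each way for the knockdown and for S34F, 5 each way elsewhere), and the 4 members with the smallest p of each list past the threshold. Where fewer passed, those with the lowest p were added up to 5 and are given as not passing. Clone and locus names were skipped. Isoforms were named by the size of the change, at most 1 per gene, with the isoform of smallest p for each gene on the list of known targets, and acceptors by the 5 smallest p in each direction among those with C or T at -3. Names outside the rule are said to be so, and some items the rule would name are not reported here.

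Same-numbered replicates were checked for pairing. Over the 21 pairs of groups, the deviations of same-numbered libraries from their group means were correlated at 0.160 to 0.571 (median 0.368) for gene expression, each above 0.1, and at 0.0134 to 0.170 for usage, above 0.1 in 10 of the 21 pairs. By the rule fixed beforehand the numbers therefore pair the samples, more clearly for expression than for usage. The main fit nevertheless leaves the pairing out, and in most comparisons it called fewer genes than a fit that includes it. The fit with replicate number as a block is an alternative, and its values stand beside results whose call it changes or whose count it moves by over 1.5 times.

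Other alternatives were the pseudocount, no filter on low values, upper quartile scaling and quantile normalization, keeping estimates not marked OK, an arcsine transform and other limits for usage, other limits for acceptors, a fit with the groups of a comparison alone, and leaving out each library. With 1 library left in a group, that library is assumed to vary like the other groups. Added after the data were seen was a fit without replicate 2 of v1 S34F and replicate 2 of v3 S34F, which lie farthest out on the first principal component. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

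The scripts were tested on simulated data in which 200 genes, isoforms or acceptors were changed. At a change of 1 on the log2 scale 68% of changed genes were called in a simulated knockdown and 85% in a simulated S34F comparison, and at a change of 2 these were 94% and 99%. For usage, 20% and 42% were called at 20 points, and 70% and 86% at 40 points. For acceptors, 9% and 31% were called at 20 points, and 58% and 84% at 40 points. Of all simulated calls, 3.03% to 8.22% were false. The simulated noise was normal and independent, without the shared deviations of same-numbered libraries, and simulated usage was not kept within its range. These rates therefore need not hold for the real data. The authors' 95% bounds gave a median half-width of 25.6% to 32.5% of the value for isoforms of at least 1 FPKM in the 14 libraries.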

Results

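RNA from A549 cells, a human lung carcinoma line, was sequenced in 14 libraries to ask how U2AF1, the small subunit of the splicing factor that binds the 3′ end of introns, shapes expression and splicing, and what its cancer mutation S34F changes. There were 7 groups of 2 libraries each. They were untreated cells, cells with an empty vector and a control siRNA, cells with an empty vector and a siRNA against U2AF1, and knockdown cells given a construct of U2AF1 isoform v1 or v3, each as wild type or S34F. Relative depth ranged from 0.814 in v1 S34F replicate 2 to 1.22 in replicate 2 of the knockdown with empty vector, and between 13734 and 14705 genes per library reached 1 FPKM. Replicates were correlated across genes at 0.965 to 0.982 for log2 expression and across isoforms at 0.853 to 0.890 for usage. A single isoform of 75 bases, from AL132768.1, took 33.1% of the FPKM sum of v1 S34F replicate 2, and MIR1260B took 8.81% in replicate 1 of the knockdown, whereas the top isoform of every other library took 0.494% to 1.06%. On the first principal component, which held 30.7% of the variance, v1 S34F replicate 2 (48.4) and v3 S34F replicate 2 (38.7) lay farthest out. Values below are means ± SD of FPKM or of usage with n = 2 libraries per group, and adjusted p-values are from limma.

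U2AF1 (ENSG00000160201, chromosome 21, 44513066 to 44527697, GRCh37) was at 135 ± 10.5 FPKM in untreated cells and 118 ± 1.37 with the control siRNA. The siRNA against it left 22.5 ± 8.97 FPKM, or 19.1% of the control, a log2 change of -2.39 (SE 0.32, adjusted p = 0.0081). With the constructs it reached 2614 ± 372 FPKM for wild-type v1, 3016 ± 1183 for v1 S34F, 2840 ± 669 for wild-type v3 and 2677 ± 795 for v3 S34F, which is 22.2, 25.6, 24.1 and 22.7 times the control. Mutant and wild-type libraries differed in U2AF1 by 0.03 on the log2 scale (SE 0.22, adjusted p = 0.973). The isoforms followed the constructs. ENST00000380276 made up 97.5 ± 0.551% of the gene's FPKM with wild-type v1 and 1.19 ± 0.116% with wild-type v3 (adjusted p = 0.00017), where ENST00000291552 stood at 2710 FPKM against 37.8 with v1. U2AF2 (ENSG00000063244, chromosome 19, 56165512 to 56186081, GRCh37), which encodes the large subunit, was at 210 ± 9.27 FPKM in untreated cells. It rose from 199.5 ± 38.2 FPKM to 306.7 ± 47.4 with the knockdown (log2 0.62, SE 0.14, adjusted p = 0.043). From 231.6 ± 8.70 FPKM with wild-type v1 it was lower at 111.1 ± 7.66 with v1 S34F, and from 201.7 ± 1.04 with wild-type v3 it was lower at 99.6 ± 4.47 with v3 S34F, an averaged log2 change of -1.03 (SE 0.10, adjusted p = 0.0025).

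**Figure D1:**
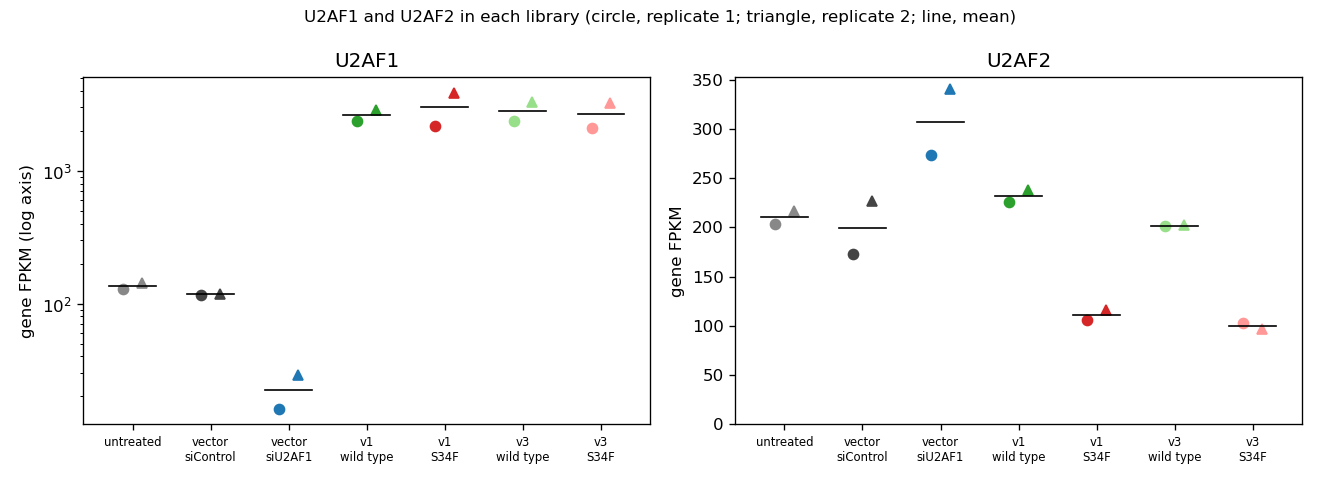
FPKM of U2AF1 (left, log axis) and U2AF2 (right, linear axis) in each library by group, with circles for replicate 1, triangles for replicate 2 and lines for group means. U2AF1 lies at 22.5 FPKM on average after the knockdown and at 2114 FPKM or more in every library with a construct, and U2AF2 is lower in both S34F groups than in the wild-type groups.

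Cells with empty vector and control siRNA were compared with untreated cells to measure the background of the procedure. The 23 p53 target genes measured all lay above untreated cells, with a median log2 change of 0.68, and as a list they rose (camera adjusted p = 1.2e-34, adjusted p = 0.0030 with an estimated correlation). CDKN1A, the cell cycle inhibitor p21, stood at 47.8 ± 7.27 FPKM without and 95.5 ± 2.11 with the treatment (adjusted p = 0.207), and FDXR, a mitochondrial reductase, at 46.0 and 104.3 FPKM (adjusted p = 0.207). The 29 genes of G2/M and mitosis fell as a list, all below untreated cells, with a median of -0.26 (adjusted p = 2.7e-18, and adjusted p = 0.0030 with an estimated correlation). SR proteins and hnRNPs fell as a list (adjusted p = 0.00029, and adjusted p = 0.04997 with an estimated correlation, 0.077 with a replicate block), and mesenchymal and TGF-beta response genes rose (adjusted p = 1.7e-05, and adjusted p = 0.027 with an estimated correlation, 0.0501 with a replicate block). The mitochondrially encoded genes, a sign of RNA quality, lay at a median of -0.91 (adjusted p = 2.3e-12, and adjusted p = 0.25 with an estimated correlation).

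In the same comparison the unfolded protein and integrated stress response list rose (adjusted p = 5.7e-07, and adjusted p = 0.054 with an estimated correlation, 0.047 with a replicate block). Another 6 lists passed with the preset correlation and were lost with an estimated one. Splice site recognition was lower (adjusted p = 0.0022, and adjusted p = 0.11 with an estimated correlation), as was G1/S and DNA replication (adjusted p = 0.00068, and adjusted p = 0.46 with an estimated correlation). Cholesterol biosynthesis was higher (adjusted p = 0.00025, and adjusted p = 0.46 with an estimated correlation), as was autophagy (adjusted p = 0.00067, and adjusted p = 0.25 with an estimated correlation). NF-kB and inflammatory cytokines were higher (adjusted p = 0.037, and adjusted p = 0.60 with an estimated correlation), as were cytosolic ribosomal proteins (adjusted p = 0.023, and adjusted p = 0.60 with an estimated correlation, 0.11 with upper quartile scaling). Of single genes, limma called 0 over all genes tested and 730 had an unadjusted p under 0.05, while 17 of the p53 targets passed adjusted over the list alone. With a replicate block, 2 genes were called, CDKN1A and GDF15, the latter outside the naming rule and chosen after its values were seen. In usage 4 isoforms were called, among them one of ABI3BP at 0 in untreated cells and 37.7 ± 5.91% with the treatment (adjusted p = 0.0029), and this count was 1 with a replicate block, where isoforms of PTPN20B (53.9 ± 3.13% and 12.5 ± 4.93%) and WNK2 (0.00138% and 24.3 ± 1.25%) had an adjusted p of 0.057.

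Knockdown of U2AF1 was compared with the control siRNA, both with the empty vector. Among the largest rises, PTBP2, the neuronal paralog of the splicing repressor PTBP1, went from 7.40 ± 1.11 to 26.9 ± 3.26 FPKM (log2 1.73, SE 0.35, adjusted p = 0.029). The hedgehog receptor PTCH1 rose from 4.47 ± 1.87 to 15.4 ± 2.53 FPKM and VAMP1, a SNARE protein of vesicle fusion, from 10.5 ± 3.54 to 34.5 ± 15.1 FPKM. OVGP1, NPPB, MTHFD2L, FAM120C, EDN2 and CITED2 also rose, by 1.11 to 1.61 on the log2 scale. The readthrough CSNK2B-LY6G5B-1181 rose by 2.09, a value that is uncertain because it shares reads with the genes it joins. The largest fall after U2AF1 itself was that of EPHB2 (chromosome 1, 23037332 to 23241818, GRCh37), an ephrin receptor kinase, from 30.2 ± 2.71 to 7.15 ± 1.81 FPKM (log2 -1.95, SE 0.21, adjusted p = 0.0035). The cytokine IL32 fell from 16.6 ± 5.34 to 5.06 ± 1.83 FPKM and TYMP, thymidine phosphorylase, from 8.03 ± 2.31 to 2.28 ± 0.116. SEC14L2, PLBD2, BAI2, PITHD1 and CCDC136 fell as well, to log2 changes between -1.58 and -1.47.

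In total 112 genes were called higher and 293 lower after the knockdown, 123 of them by at least 2 times, and 2689 genes had an unadjusted p under 0.05. With a replicate block these calls were 668 and 1013. The total of 405 was 43 without replicate 1 of the knockdown, 15 without its replicate 2 and 19 without replicate 2 of the control siRNA. SR proteins and hnRNPs rose as a list, 25 of 27 members above the control with a median of 0.28 (adjusted p = 3.4e-07, and adjusted p = 0.029 with an estimated correlation, 0.068 with a replicate block). Of its members PTBP2 alone passed over all genes, and 11 higher and 1 lower passed adjusted over the list alone. PTBP1 was at 224 ± 28.8 and 312 ± 29.7 FPKM (adjusted p = 0.064, or 0.021 with a replicate block). Mitochondrially encoded genes lay higher in 15 of 15 (median 0.63, adjusted p = 0.00058, and adjusted p = 0.64 with an estimated correlation), as did 27 of 31 cytosolic ribosomal proteins (adjusted p = 0.00033, and adjusted p = 0.64 with an estimated correlation). The lists of SR proteins and hnRNPs and of mitochondrially encoded genes had been lower with the control siRNA than in untreated cells. The same control libraries serve here, so low values in them alone could make both lists rise. Of the nonsense-mediated decay factors 12 of 16 lay higher (adjusted p = 0.032, and adjusted p = 0.41 with an estimated correlation), with 3 passing adjusted over the list alone. Of the interferon-stimulated genes 3 of 14 lay above the control (adjusted p = 0.036, and adjusted p = 0.41 with an estimated correlation), and IFI6 fell from 5.54 ± 1.26 to 2.08 ± 0.215 FPKM (adjusted p = 0.033).

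Isoform usage after the knockdown changed for 54 isoforms of 48 genes, 39 with more and 15 with less usage, or 39 and 23 with a replicate block, which kept 40 of the 54. WNK4, a kinase of ion transport, had 90.1 ± 13.96% of its FPKM in ENST00000246914 with the control siRNA and 17.6 ± 1.05% with the knockdown (-72.5 points, adjusted p = 0.042), while untreated cells had 39.2 ± 17.01%. FANCB, of the Fanconi anemia DNA repair complex, went from 8.86 ± 1.85% to 64.5 ± 3.57% in ENST00000324138 (adjusted p = 0.042), and SNAP25, a SNARE protein, from 8.80 ± 3.19% to 54.7 ± 12.7% in ENST00000254976 (adjusted p = 0.042, or 0.057 with a replicate block). PDGFB dropped from 42.4 ± 2.76% to 3.42 ± 3.45% in ENST00000381551 (adjusted p = 0.023). Isoforms of C16orf74, FAM120C and TMEM126B gained 52.6, 47.9 and 41.1 points. Among the calls that a replicate block took away were those for C1orf228 (-61.7 points, 0.055), FAM161A (0.057) and CDC25A (0.055). The count of 54 was 32 without replicate 1 of the control siRNA (7 with more and 25 with less usage), 5 without its replicate 2 (1 and 4) and 17 without replicate 2 of the knockdown (16 and 1). An arcsine transform gave 5 with more and 8 with less, so the excess of gains depends on the scale and on single libraries.

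Wild-type re-expression was measured as the mean of wild-type v1 and v3 against the knockdown. The labels call it overexpression, and U2AF1 stood at 22.2 and 24.1 times the control. The comparison therefore cannot tell a return of U2AF1 from its excess. FECH, ferrochelatase of heme synthesis, rose from 23.0 ± 3.55 FPKM to 62.3 ± 4.77 with v1 and 56.5 ± 4.76 with v3 (log2 1.33, SE 0.12, adjusted p = 0.0018). IL32 rose from 5.06 to 12.3 and 18.5 FPKM, and UBLCP1 from 15.1 to 36.7 and 41.4. SLX1A rose by 1.47, which is uncertain because its near-identical copy SLX1B can share its reads. Genes raised by the knockdown fell, among them PTBP2 (to 9.78 and 9.57 FPKM, adjusted p = 0.0485), VAMP1 (to 10.7 and 9.35 FPKM), OVGP1 and the readthrough CSNK2B-LY6G5B-1181. SNAP25 fell from 27.6 to 9.48 and 8.56 FPKM. U2AF2 was at 231.6 and 201.7 FPKM against 306.7 (log2 -0.50, adjusted p = 0.077, or 0.016 with a replicate block). In all, 148 genes were called higher and 55 lower, or 91 and 45 with quantile normalization and 707 and 363 with a replicate block. The total of 203 was 19 without replicate 1 of the knockdown, 5 without its replicate 2 (2 higher and 3 lower), 57 and 40 without those of wild-type v1, and 52 and 39 without those of wild-type v3.

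Of the p53 targets 23 of 23 lay above the knockdown with wild-type U2AF1 (median 0.56, adjusted p = 1.1e-15, and adjusted p = 0.019 with an estimated correlation, 0.10 with a replicate block). Among them 5 were called over all genes and 18 adjusted over the list alone. DDB2, a DNA damage sensor, rose from 44.5 ± 2.26 FPKM to 94.3 ± 1.96 with v1 and 99.3 ± 8.40 with v3 (adjusted p = 0.0070), and CDKN1A from 96.6 ± 1.98 to 154.2 ± 30.4 and 175.5 ± 14.5 (adjusted p = 0.023). FDXR and SESN1 rose by 0.99 and 0.91. The knockdown itself had not moved the p53 targets as a list (median -0.10, camera adjusted p = 0.29). SR proteins and hnRNPs fell as a list, with 4 of 27 above the knockdown (adjusted p = 4.1e-09, and adjusted p = 0.016 with an estimated correlation), including PTBP1, from 311.6 to 191.1 and 198.5 FPKM (adjusted p = 0.019). NF-kB and inflammatory cytokines lay higher in 17 of 18 (median 0.90, adjusted p = 4.5e-06, and adjusted p = 0.36 with an estimated correlation), with 4 passing adjusted over the list alone. Histones lay higher in 12 of 13 (adjusted p = 0.0012, and adjusted p = 0.36 with an estimated correlation). The lists of G2/M and mitosis (adjusted p = 0.00054, and adjusted p = 0.18 with an estimated correlation) and of G1/S and DNA replication (adjusted p = 7.8e-05, and adjusted p = 0.36 with an estimated correlation) lay lower. A replicate block added the unfolded protein and integrated stress response, higher (0.065 without and 0.026 with it), and cholesterol biosynthesis, lower (0.0505 without and 0.044 with it, 0.046 with upper quartile scaling), and neither passed with an estimated correlation (adjusted p = 0.39 and 0.58, or 0.42 and 0.61 with a replicate block).

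The knockdown and the re-expression share the knockdown libraries, which alone makes their changes oppose each other. Across genes, which are not independent replicates, the correlation was -0.63 against -0.58 for simulated unchanged groups (100 draws), and the covariance was -0.0819 against -0.0395. Of the genes called for the knockdown, 95.3% had the opposite sign on re-expression against 96.1% in the simulation. There were 26 genes called up and then down, where independent lists would give 0.433, and 78 called down and then up, where they would give 3.05. The shared libraries break that independence, and the overlap that they alone would give was not computed. These counts therefore cannot show an excess. For usage 114 isoforms of 104 genes were called, 27 with more and 87 with less usage, or 41 and 113 with a replicate block, which kept 108 of the 114, while an arcsine transform turned this balance over, to 34 and 17. FANCB ENST00000324138 went from 64.5% to 13.2 ± 18.7% with v1 and 0.00066% with v3 (adjusted p = 0.014). Its wild-type v1 libraries stood at 7.5e-30% and 26.5%, so that mean is uncertain. SNAP25 ENST00000254976 went from 54.7% to 5.73 ± 8.11% and 5.88 ± 1.45% (adjusted p = 0.014) and C16orf74 from 80.7% to 32.9% and 33.4% (adjusted p = 0.020). The isoforms of MSANTD2 and PIH1D2 changed by -49.8 and -56.0 points, the latter with an adjusted p of 0.051 under a replicate block. The usage correlation was -0.65 against -0.58 simulated, with 34 isoforms up and then down and 5 down and then up, where independent lists would give 0.0813 and 0.0097. The limit given for genes holds for these isoform counts too. The 114 calls were 40 without replicate 2 of the knockdown, 66 and 20 without replicates 1 and 2 of wild-type v1, and 8 and 6 without those of wild-type v3.

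S34F was compared with the wild type within each construct and the changes were averaged. NCAPG2 (ENSG00000146918, chromosome 7, 158424003 to 158497520, GRCh37), a condensin subunit, fell from 36.6 ± 1.25 FPKM to 11.7 ± 0.607 in v1 and from 34.2 ± 2.26 to 12.7 ± 1.73 in v3 (log2 -1.47, SE 0.08, adjusted p = 3.0e-05). OIP5, a centromere protein, fell from 11.8 ± 0.982 to 2.97 ± 1.36 FPKM and from 11.3 ± 1.65 to 4.10 ± 2.71. HACL1, a lyase of peroxisomal alpha-oxidation, fell from 22.5 to 10.2 and from 26.8 to 12.1 FPKM (log2 -1.08, adjusted p = 0.00041). Complement C5 fell from 22.5 to 10.0 and from 22.9 to 9.83 FPKM, and the endolysosomal cation channel TPCN1 from 20.8 to 8.35 and from 17.9 to 8.92. SLC17A3, PON3, PDGFD and TFCP2 fell too, to log2 changes between -1.23 and -1.03. GUCA1B rose from 0.961 ± 0.188 to 8.26 ± 3.12 FPKM and from 0.805 ± 0.229 to 5.85 ± 2.42 (log2 2.04, SE 0.23, adjusted p = 0.0029). The sterol regulator INSIG1 rose from 17.1 ± 3.62 to 35.2 ± 3.97 and from 15.4 ± 4.15 to 29.4 ± 5.79 FPKM (adjusted p = 0.012), and EYA3 from 6.26 to 12.4 and from 6.01 to 12.3. FERMT3, FIGF, KCND1 and WNK4 rose by 1.08 to 1.21.

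Rises of CNTF (1.68), CSNK2B-LY6G5B-1181 (1.67) and STARD13-AS (1.25) are uncertain, since the first is overlapped by a readthrough gene, the next is a readthrough and the last is antisense to STARD13. In total 83 genes were called higher and 181 lower, 37 by at least 2 times, and 2266 genes had an unadjusted p under 0.05. With a replicate block 466 and 670 were called. The 264 calls were 63 and 58 without replicates 1 and 2 of wild-type v1, 75 and 47 without those of wild-type v3, 100 without v1 S34F replicate 2 and 77 without v3 S34F replicate 2. Without both of these mutant libraries, which lie apart on the first principal component, 56 genes were called, a setting chosen after the data were seen. With the knockdown, 9 genes were called up in both, against 0.653 for independent lists, and 8 down in both, against 3.73. Opposite calls also exceeded independent lists, with 4 genes up in the knockdown and down with S34F, against 1.42, and 5 the other way, against 1.71, and across genes the correlation of the changes was 0.003. HACL1 was among those down in both (knockdown -0.69, adjusted p = 0.019), named here after its values were seen.

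Of the lists, cholesterol biosynthesis rose with S34F, 19 of 23 members lying higher with a median of 0.33 (adjusted p = 3.7e-05, and adjusted p = 0.90 with an estimated correlation). INSIG1 and MVK, mevalonate kinase (9.71 to 18.1 FPKM in v1 and 10.4 to 16.6 in v3, adjusted p = 0.038), were called over all genes, and 7 passed adjusted over the list alone. NRF2 targets fell, with 4 of 22 above the wild type and a median of -0.12 (adjusted p = 0.019, and adjusted p = 0.90 with an estimated correlation). The aldehyde dehydrogenase ALDH3A1 fell from 574 ± 8.76 to 374 ± 54.9 FPKM in v1 and from 532 ± 18.03 to 392 ± 87.3 in v3 (adjusted p = 0.043), and 2 members passed adjusted over the list alone. The other lists did not pass. Their adjusted p was 0.88 for splice site recognition, 0.96 for nonsense-mediated decay factors, 0.27 for genes known to splice differently, 0.35 for G2/M and mitosis, 0.30 for G1/S and DNA replication, 0.083 for autophagy and 0.62 for mitochondrially encoded genes. It was 0.575 for p53 targets, ribosomal proteins, mesenchymal genes and markers of leukocytes and endothelium (2 of 15 measured), 0.61 for histones, interferon-stimulated genes and NF-kB, and 0.46 for the unfolded protein response. It was 0.79 for SR proteins and hnRNPs, epithelial genes, glycolysis, alveolar markers (7 of 20 measured) and fibroblast markers (2 of 12 measured).

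Within v1 alone S34F had 4 genes called higher and 21 lower, or 9 and 23 with quantile normalization, 22 and 29 without a filter on low values and 80 and 229 with a replicate block. TDRP fell from 15.0 ± 1.20 to 6.24 ± 0.120 FPKM, the cap-binding protein NCBP1 from 24.6 ± 2.27 to 10.8 ± 0.754 and the kinetochore protein CENPK from 45.5 ± 1.36 to 20.8 ± 4.22, with adjusted p of 0.026, 0.021 and 0.021. The 25 calls were 3 without either replicate of wild-type v1 and 5 without v1 S34F replicate 2 (3 higher and 2 lower). Within v3 alone 1 gene was called higher and 2 lower, or 14 and 7 without that filter and 19 and 50 with a replicate block. They were NCAPG2 (adjusted p = 0.0023), HACL1 (adjusted p = 0.012) and CTC-246B18.10 (log2 3.84, SE 0.44, adjusted p = 0.014), the last outside the naming rule and chosen after its values were seen. These 3 calls were 6 without replicate 1 of v3 S34F (5 higher and 1 lower) and 7 without its replicate 2 (6 and 1). U2AF2 changed in v1 (log2 -1.05, adjusted p = 0.021), while in v3 its change of -1.01 had an adjusted p of 0.064, or 0.0065 with a replicate block. Cholesterol biosynthesis rose in v1 (adjusted p = 2.5e-05, and adjusted p = 0.59 with an estimated correlation) and in v3 (adjusted p = 0.00069, and adjusted p = 0.98 with an estimated correlation). NRF2 targets (adjusted p = 0.0054, and adjusted p = 0.59 with an estimated correlation) and G1/S genes (adjusted p = 0.012, and adjusted p = 0.59 with an estimated correlation) fell in v1. In v3 neither list passed (camera adjusted p = 0.32 for NRF2 targets and 0.95 for G1/S genes).

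The difference between the S34F changes in v3 and v1 was tested itself. Limma called 0 genes, and 101 had an unadjusted p under 0.05. The lowest p was that of the kinase CDK2, at 43.6 ± 4.66 and 28.4 ± 0.706 FPKM in v1 and 35.5 ± 0.0108 and 37.3 ± 2.31 in v3 (unadjusted p = 0.0015, adjusted p = 1). Cyclin CCNA2 stood at 38.6 ± 4.26 and 17.9 ± 2.05 FPKM in v1 and 36.8 ± 0.722 and 27.5 ± 3.55 in v3 (unadjusted p = 0.0048, adjusted p = 1). Across genes the changes in v1 and v3, which share no library, correlated at 0.52, and 25 of the 25 genes called in v1 had the same sign in v3.

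**Figure D2:**
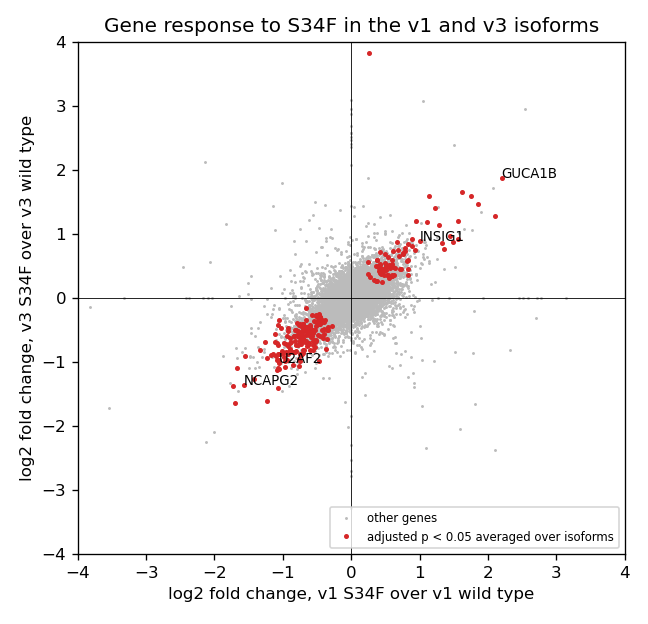
Log2 change with S34F in v1 (horizontal axis) against that in v3 (vertical axis), one point per gene tested, red for genes called in the averaged comparison, with 5 genes outside the axes. NCAPG2 and U2AF2 lie low on both axes and GUCA1B and INSIG1 high, along a correlation of 0.52.

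Isoform usage changed with S34F for 284 isoforms of 241 genes, 182 with more and 102 with less usage, or 246 and 169 with a replicate block, which kept 272 of the 284, and 129 and 123 with an arcsine transform. In STRAP, ENST00000419869 (chromosome 12, 16035329 to 16056412, GRCh37) fell from 87.0 ± 3.73% to 41.8 ± 24.3% in v1 and from 86.1 ± 2.62% to 44.0 ± 21.9% in v3 (-43.7 points, SE 7.94, adjusted p = 0.048). COX18, a factor of cytochrome oxidase assembly, gained an isoform annotated as a target of nonsense-mediated decay, ENST00000449739, from 3.43 ± 4.85% to 48.8 ± 15.1% and from 6.06 ± 8.57% to 47.9 ± 20.3% (adjusted p = 0.035). Isoforms of the same class gained 45.0 points in ULK4 and 38.8 in FZD6. In LIAS, lipoic acid synthetase, ENST00000261434 fell from 58.3 ± 1.44% to 28.98 ± 11.4% and from 79.5 ± 2.27% to 29.3 ± 9.13% (adjusted p = 0.019), and FBXO4 changed by -41.9 points. Isoforms of SMPDL3A (52.96 points), PAQR6 (46.9), DEPDC4 (46.3) and GPR157 (-41.4) passed here, with adjusted p of 0.051, 0.054, 0.053 and 0.052 under a replicate block. The 284 calls were 33 and 12 without replicates 1 and 2 of wild-type v1, 12 and 7 without those of wild-type v3, 61 without v1 S34F replicate 2, 31 without v3 S34F replicate 2 and 49 without both mutant libraries. Losses outnumbered gains without replicate 2 of wild-type v1 (5 with more and 7 with less usage) or of wild-type v3 (3 and 4).

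A list of genes known to splice differently with mutant U2AF1 had 70 isoforms of 15 genes tested, of which 5 isoforms of 4 genes passed over all isoforms, or 8 isoforms with a replicate block, and 20 of 12 genes adjusted over the list alone. Besides STRAP these were BCOR, a transcriptional corepressor, whose ENST00000378444 fell from 54.1 ± 2.09% to 12.8 ± 4.26% in v1 and from 44.8 ± 14.4% to 12.4 ± 8.75% in v3 (adjusted p = 0.021), CTNNB1, beta-catenin, whose ENST00000396185 rose from 35.6 ± 0.987% to 60.9 ± 8.31% and from 34.8 ± 2.00% to 63.2 ± 4.64% (adjusted p = 0.023), and DEK, whose ENST00000244776 rose from 22.4 ± 4.83% to 47.1 ± 0.793% and from 20.7 ± 0.736% to 43.8 ± 0.458% (adjusted p = 0.039). Over all isoforms, those of ASUN (17.2 points, adjusted p = 0.0505) and PCBP2 (-11.1 points, adjusted p = 0.0504) did not pass in the main fit and passed with a replicate block, at 0.046 and 0.037. Within v1 limma called 0 isoforms with 3425 at an unadjusted p under 0.05, and within v3 0 with 3074. The lowest p in v1 was that of UBE2Q2 ENST00000569423, at 27.9 ± 0.429% and 65.2 ± 2.00% (adjusted p = 0.053), and it stood at 15.9 ± 0.772% and 47.5 ± 1.15% in v3 (adjusted p = 0.12). For the difference between v3 and v1 limma called 0 isoforms, with 1325 at an unadjusted p under 0.05.

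**Figure D3:**
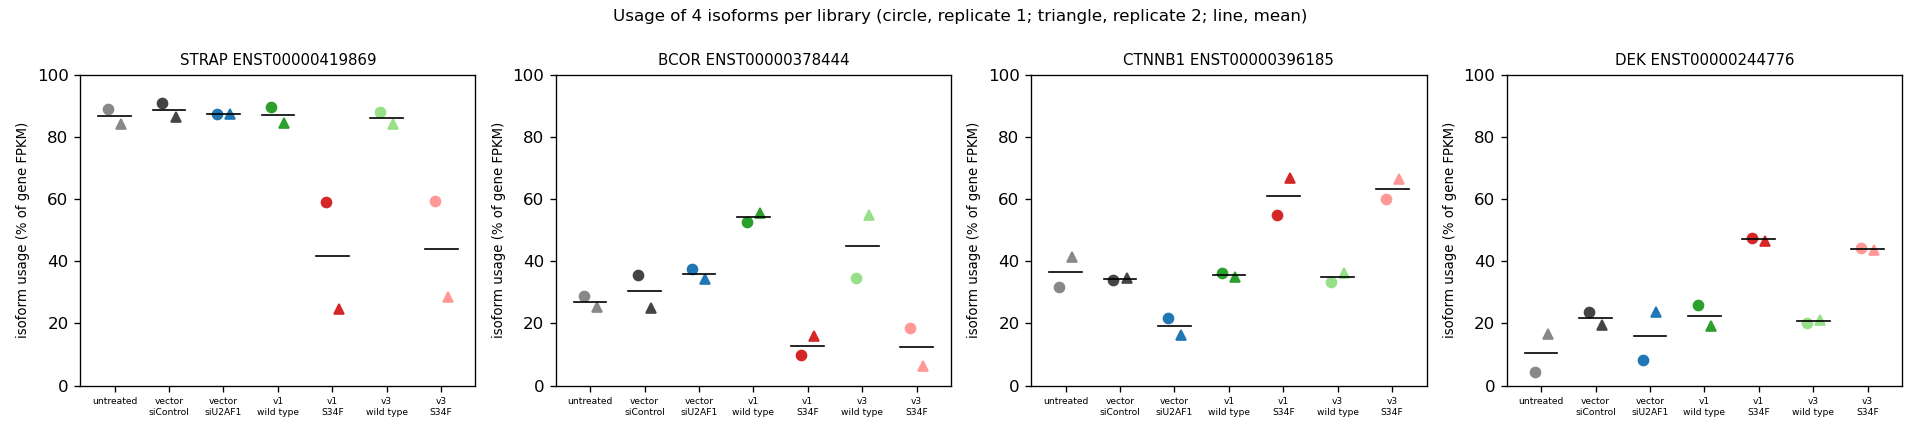
Usage in each library, as percent of the gene's FPKM, of 1 isoform each of STRAP, BCOR, CTNNB1 and DEK by group, with lines for group means. The S34F groups lie lower for STRAP and BCOR and higher for CTNNB1 and DEK, and the STRAP values of S34F replicates are spread with an SD of up to 24.3 points.

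Acceptors, the 3′ splice sites, were sorted by the intron base at position -3, next to the AG. With S34F 578 genes had an acceptor with a change of at least 5 points and an unadjusted p under 0.01. Of those with T at -3, 208 were used less and 20 more (91.2% less), while of those with C 81 were used less and 189 more (30.0% less), and of those with A 16 less and 58 more. The odds ratio between T and C was 24.1 (95% interval 14.01 to 43.2, two-sided Fisher's exact test p = 1.8e-47). Here and below this exact test counts acceptors measured in the same libraries as independent. Its p and interval therefore do not measure the spread between samples. By the same exact test it was 13.2 (7.17 to 25.4, p = 5.7e-22) in v1 and 11.8 (5.92 to 25.1, p = 2.8e-16) in v3, and 0.658 (0.197 to 2.18, p = 0.585) for acceptors that differed between v3 and v1. In the background comparison of vector and untreated cells the exact test gave 1.30 (0.506 to 3.32, p = 0.662). Over the 4 pairs of mutant and wild-type libraries, the mean change of all acceptors with T was -3.53 ± 0.946 points and of those with C 0.570 ± 0.334.

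After the knockdown 331 acceptors were used less and 132 more. Of those with T, 64 were used less and 28 more (69.6% less), and of those with C 246 less and 74 more (76.9% less), an odds ratio of 0.688 (0.401 to 1.20, Fisher's exact p = 0.171). By the same exact test that ratio was 0.499 (p = 0.0032) with a replicate block, 0.481 (p = 0.010) without replicate 1 of the knockdown and 1.21 (p = 0.52) without replicate 1 of the control siRNA. On re-expression 162 acceptors were used less and 370 more, with a ratio of 1.29 (0.774 to 2.11, exact p = 0.32).

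Single acceptors passed with S34F over all acceptors in 156 cases with more and 261 with less use, 657 in total with a replicate block. Acceptors of the same isoforms share their values, so these counts and those below can hold the same isoform estimate more than 1 time. With T at -3, the acceptor of KCTD9 at chromosome 8, 25439664 (GRCh38) fell from 77.03% to 34.7% in v1 and from 75.4% to 40.3% in v3 (adjusted p = 0.012), that of SECISBP2L at chromosome 15, 49019552 from 86.0% to 57.9% and from 99.99% to 66.7% (adjusted p = 0.0058), and that of CRYZ at chromosome 1, 74707204 from 90.9% to 60.1% and from 92.5% to 67.2% (adjusted p = 0.018). Acceptors of MYEOV and CCP110 changed by -19.6 and -29.1 points. With C at -3, the acceptor of BCOR at chromosome X, 40063850 rose from 43.1% to 86.9% and from 53.8% to 87.2% (adjusted p = 0.018), and that of SCAF4 at chromosome 21, 31685174 from 17.8% to 46.5% and from 16.7% to 45.3% (adjusted p = 0.0079). That of fibronectin FN1 at chromosome 2, 215372300 rose from 16.4% to 49.1% and from 25.0% to 37.1% (adjusted p = 0.018). Those of PLXNB3 and ARHGAP11A gained 24.7 and 19.7 points. After the knockdown 28 acceptors passed, 15 with more and 13 with less use, and 69 passed with a replicate block. That of PLXNB3 fell from 100% to 67.1% (adjusted p = 0.028), and those of FGFR1 (27.7% to 66.9%, adjusted p = 0.025), with C, and of PTK2 (29.2% to 74.3%, adjusted p = 0.032) and GIT1 (10.0% to 52.2%, adjusted p = 0.016), with T, rose. Those of REC8 (0% to 80.7%, and 58.1% in untreated cells) and DLX1 (45.1 points) rose as well (adjusted p = 0.039 for both). Acceptors of MPI (76.5% and 41.9%), CPSF3L (89.3% and 57.04%), TMEM234 (36.5% and 5.48%) and DNAJB12 (78.6% and 52.4%) had the next lowest p among those used less with a known C or T at -3, 1 per gene. They did not pass (adjusted p = 0.053), while with a replicate block they passed at 0.029, 0.037, 0.043 and 0.037.

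**Figure D4:**
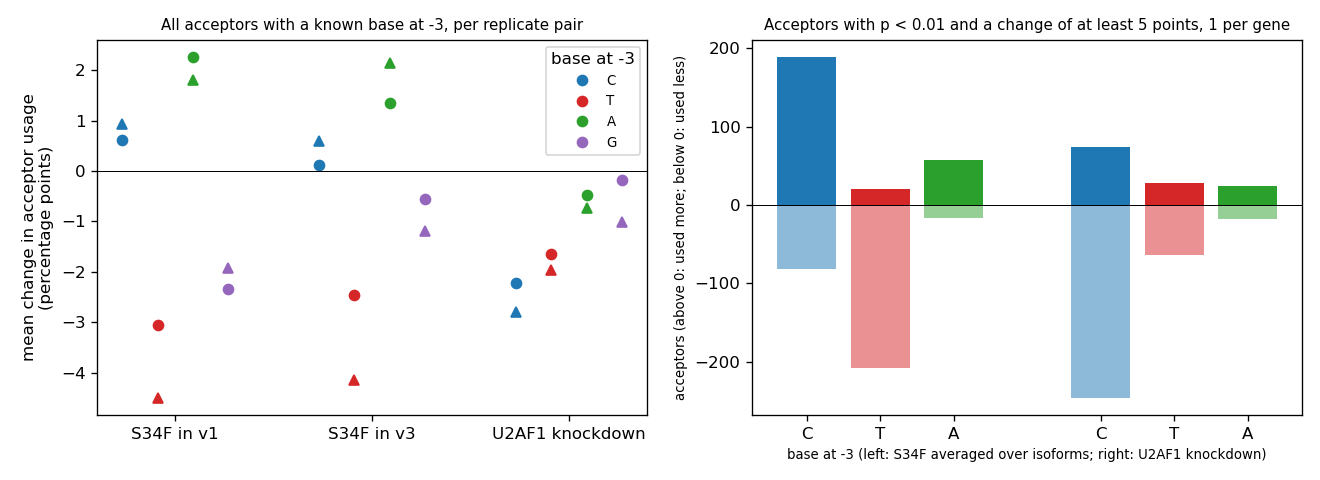
Left, mean change in usage of all acceptors in percentage points by base at -3 for each replicate pair, for S34F in v1, S34F in v3 and the knockdown. Right, number of acceptors with a change that were used more (above 0) or less (below 0) by base, for S34F averaged and for the knockdown, where T makes up 208 of the acceptors used less with S34F and 64 after the knockdown.

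Wild-type v3 was compared with wild-type v1 to ask whether the isoforms of U2AF1 act differently. U2AF1 stood at 2840 and 2614 FPKM and U2AF2 at 201.7 and 231.6 FPKM (adjusted p = 1 for both). Limma called 0 genes with 150 at an unadjusted p under 0.05. The lowest p was that of RDM1, at 5.04 ± 0.155 FPKM with v1 and 2.44 ± 0.686 with v3, then MLLT10, at 38.4 ± 1.16 and 24.8 ± 0.326, and DCAF6, at 32.1 ± 0.915 and 20.1 ± 3.03 FPKM (adjusted p = 1 for each). The isoforms called in usage were 2, both of U2AF1 itself. As lists, p53 targets and NF-kB genes lay higher with v3, each at an adjusted p of 0.012, as did the unfolded protein response (0.027) and ribosomal proteins (0.029, or 0.26 with upper quartile scaling). G1/S genes (0.012), splice site recognition (0.027) and NRF2 targets (0.046) lay lower. None of the 7 held with an estimated correlation, where the lowest adjusted p was 0.70, 0 of their members were called by limma, and splice site recognition (0.051), NRF2 targets (0.064) and ribosomal proteins (0.051) were lost with a replicate block.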

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

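The tests of the acceptor pattern named below were planned before the result was seen, except the one on readable bases, which was chosen after it, and the naming of KLHL22 and CMSS1 followed a rule on the difference between constructs.

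Acceptors of 2 genes stood out because the change with S34F differed between v3 and v1 by the test of the difference itself. An acceptor of KLHL22 (chromosome 22, 20456467, GRCh38) differed by -94.49 points (SE 10.5, adjusted p = 0.041), a call that a replicate block took away (adjusted p = 0.099). It was used at 98.02% and 99.44% in the v1 S34F libraries and at 0% to 21.8% in all others, in isoforms with a summed mean of 2.86 FPKM. In CMSS1, 4 acceptors on chromosome 3 (100011703, 100023319, 100025428 and 100039775, GRCh38) differed by 103.17 points (SE 3.84, adjusted p = 2.5e-06). They were used at 99.8% and 99.9% in the v3 S34F libraries and at up to 5.07% in all others, in isoforms with a summed mean of 1.95 FPKM. All 4 had the same usage in every library, so they count as 1 measurement. The isoforms that span these acceptors are measured at low levels here.

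The use of acceptors with T at -3 fell with S34F where that of acceptors with C did not. If the choice of acceptors with readable bases made this pattern in any comparison, the background comparison of vector and untreated cells would show it too. Its odds ratio was 1.302 (upper bound 3.32, below the lower S34F bound of 14.01). However, 0 acceptors were called there and 141 met the limits on p and points. The test therefore cannot exclude a choice that matters only where usage responds. If v1 S34F replicate 2, the library farthest out, made the pattern, the S34F ratio would approach 1 without that library, but it was 18.65. Of the 35 splits of the 8 construct libraries into 4 and 4, 1 gave a Fisher p as small, the real one (6.5e-41, against 2.5e-07 for the next). Only 18 of these splits hold as many libraries of each replicate number, too few to exclude chance. A hypothesis that stays open is that S34F disfavors acceptors with T next to the AG, which may hold only for the alternative acceptors measured here.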

How the results depend on the processing

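The settings without both mutant replicates 2 were chosen after the data were seen, and all others were planned. With 2 libraries per group, most counts of calls move when a library is left out, and the cause of the changes below was not tested, except that leaving out libraries or groups leaves fewer degrees of freedom. Absolute depth is unknown, so what depth limits was not measured. With 1 library left in a group, that library is assumed to vary like the other groups.

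The T against C odds ratio of acceptors with S34F, 24.1, kept its direction and stayed past the threshold in all settings run, from 9.23 without both mutant replicates 2 to 76.56 with acceptors past an adjusted p of 0.05, and from 15.78 to 23.03 when 1 library was left out. That of the knockdown, 0.688, passed with a wider set at an unadjusted p under 0.05 (0.6518, p = 0.0055 by Fisher's exact test) and with a replicate block (0.4987), and with 1 library left out it ranged from 0.4814 without replicate 1 of the knockdown to 1.207, reversed, without replicate 1 of the control siRNA. With acceptors past an adjusted p of 0.05 it was 0 (p = 1 by Fisher's exact test). Of the 154 list tests 36 passed with the preset correlation, 7 with an estimated one and 35 with upper quartile scaling.

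With a replicate block, called genes went from 405 to 1681 for the knockdown, from 264 to 1136 for S34F averaged, from 25 to 309 in v1, from 3 to 69 in v3, from 203 to 1070 for the re-expression and from 0 to 2 for the vector, and called isoforms for the vector from 4 to 1. Of the named calls the block kept 71 of 71 genes, 21 of 32 isoforms and 16 of 16 acceptors. It kept 40 of 54 called isoforms for the knockdown, 272 of 284 for S34F averaged and 108 of 114 for the re-expression, 409 of 417 called acceptors for S34F averaged and 4 of 5 for the difference. Its other changes were added calls and those given beside their results, and it took away no other call of a comparison. Of the 32 named isoform calls, 19 were in genes with a mean of at least 5 FPKM, and the rest were in genes below it. The acceptor counts can hold the same isoform estimate more than 1 time.

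Without a filter on low values, called genes numbered 241 for the knockdown, 51 for S34F in v1 (22 higher and 29 lower), 21 in v3 (14 and 7), 15 for the difference between v3 and v1, 10 for wild-type v3 against v1 and 19 for the vector. A pseudocount of 0.1 gave 1 gene for the difference and 1 for wild-type v3 against v1. With the groups of a comparison alone limma called 0 genes for the knockdown (2611 at an unadjusted p under 0.05), 39 for S34F averaged, 0 in v1 (925), 0 in v3 (756), 2 for the difference, 20 for the re-expression and 1 for the vector. For usage the same setting gave 0 isoforms for the knockdown (3979 at an unadjusted p under 0.05), S34F averaged (5009), the re-expression (4957), wild-type v3 against v1 (2042) and the vector (1721). An arcsine transform gave 13 isoforms for the knockdown, 51 for the re-expression and 0 for the vector (2178 unadjusted). With genes of at least 5 FPKM there were 112 for the knockdown, 540 for S34F averaged, 32 in v1, 235 for the re-expression and 1 for the vector. Usage from 1 to 99 percent gave 197 for the knockdown, 67 for S34F in v1, 15 in v3, 9 for the difference, 307 for the re-expression, 29 for wild-type v3 against v1 and 19 for the vector. Without both mutant replicates 2, S34F averaged had 56 genes and 49 isoforms. Upper quartile scaling and quantile normalization kept each total of called genes within 1.5 times. By direction, quantile normalization took the genes called higher from 148 to 91 for the re-expression and from 4 to 9 for S34F in v1.

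With each library left out in turn, called genes ranged from 15 to 274 for the knockdown, 47 to 332 for S34F averaged, 3 to 37 in v1, 2 to 7 in v3, 1 to 6 for the difference, 5 to 57 for the re-expression, 1 to 3 for wild-type v3 against v1 and 2 to 7 for the vector. Called isoforms ranged from 5 to 59 for the knockdown, 7 to 419 for S34F averaged, 8 to 47 in v1, 3 to 10 in v3, 2 to 11 for the difference, 6 to 86 for the re-expression, 7 to 10 for wild-type v3 against v1 and 7 to 27 for the vector. Of the named calls, 9 of 71 genes, 0 of 32 isoforms and 3 of 16 acceptors passed in every setting run for them, which for acceptors were the replicate block and the left-out libraries alone, and none reversed in any.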

Other observations

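The tests of U2AF1 levels and of U2AF2 isoforms, and the genes named in the next 2 paragraphs, were chosen after the results were seen, and the other tests were planned.

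Factors of splice site recognition moved in opposite ways as single genes. After the knockdown RBM39, a splicing factor related to U2AF2, rose by 1.01 on the log2 scale (adjusted p = 0.0017 by limma) and SF1, the branch point binding protein, by 0.80 (adjusted p = 0.018), while the helicase DDX46 fell by 0.71 (adjusted p = 0.016). With wild-type re-expression RBM39 fell by 0.80 (adjusted p = 0.0034) and DDX46 rose by 0.72 (adjusted p = 0.011), against the same knockdown libraries. RBM39 also rose by 0.41 with S34F (adjusted p = 0.015). The knockdown lowered TGFBI, a matrix protein induced by TGF-beta, by a log2 change of -1.37 (adjusted p = 0.0087), the integrin ITGA5 by -0.64, the phosphofructokinase PFKP by -1.17 (adjusted p = 0.0097) and the glucose transporter SLC2A1 by -0.46 (adjusted p = 0.034). The lists of mesenchymal (camera adjusted p = 0.39) and glycolysis genes (0.24) did not pass there. Mesenchymal genes had risen as a list in the same control libraries over untreated cells, so high values in them alone could make members fall.

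With S34F several genes of cell division fell although their lists did not pass. Topoisomerase TOP2A changed by -0.84 (adjusted p = 0.0029), the spindle checkpoint kinase BUB1B by -0.57 (adjusted p = 0.023), DLGAP5, of the mitotic spindle, by -0.42 (adjusted p = 0.021) and RRM1, of ribonucleotide reductase, by -0.67 (adjusted p = 0.0071). STRAP, whose isoform usage shifted, changed by -0.46 as a gene (adjusted p = 0.036).

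U2AF2 was lower with S34F in both constructs. Scaling of the libraries is argued against as the cause, since the change was -1.054 with upper quartile scaling and -1.020 with quantile normalization. More U2AF1 in the mutant libraries was not seen, as the difference was 0.029 on the log2 scale (at most 0.474 with 2 standard errors added). The size asked for was set after the results were seen, so the test excludes no cause. Whether a difference of up to 0.474 could lower U2AF2 was not tested. A shift of U2AF2 towards an unstable isoform stays open and may play a part. ENST00000592874, annotated as a target of nonsense-mediated decay, stood at 2.07% and 8.09% of U2AF2 in v1 and at 2.25% and 11.1% in v3, wild type and S34F, with an adjusted p of 0.05313 among isoforms of 1 to 99 percent usage, a range widened after none of 5 to 95 percent had gained usage.

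For the genes called with S34F, the 8 construct libraries in 2 groups of 4 gave 360 called genes. Of their 35 splits 2 gave as many, so chance cannot be excluded by this test, the other being the split by replicate number, with 3231, which points to a structure of the samples. With a replicate block, over the 18 splits that hold as many libraries of each number, the real one gave 2481 and the highest of the others 1. Without v1 S34F replicate 2 the median change of the called genes was 93.08% of that with it. These genes were called with that library in the fit, which favors genes whose replicates agree. The value therefore cannot exclude that this library shaped which genes were called. For isoforms 1 of the 35 splits gave as many, the real one, with 126 against 5. Over those 18 splits with a block it gave 215 against 4. So few splits cannot exclude chance, and they show only that the real split was the most extreme. An effect of S34F on expression remains a hypothesis, and replicate number may mark a shared day or batch that is not stated.

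It was also asked whether the exon base after the acceptor bears on the direction of change with S34F. The odds ratio for G against other bases at +1 was 1.161 (0.825 to 1.64, p = 0.40 by Fisher's exact test), an interval within the range set beforehand for no effect. A further hypothesis, that S34F favors isoforms not annotated as protein coding, was met in the test. That class includes targets of nonsense-mediated decay, of which 21 gained and 6 lost usage. Of the called isoforms not annotated as protein coding 58 gained and 17 lost usage, against 112 and 82 of the coding ones, an odds ratio of 2.49 (1.31 to 4.91, p = 0.0030 by Fisher's exact test), and it may reflect how isoforms are annotated as well. The test counts isoforms as independent, although usages within a gene are tied. The excess of gains with S34F shrank with an arcsine transform, for which the test was not repeated. For the knockdown the ratio was 0.7311 (0.0971 to 8.90, p = 0.66 by Fisher's exact test), too wide to decide.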
